A study of Mus musculus with 8 samples.

How the data were processed

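Gene expression was measured in liver RNA of 8 female Ames dwarf mice, each on its own Affymetrix mouse U74Av2 array, a 1-colour oligonucleotide array. Per the labels, the mice ate a standard pelleted diet without restriction and were killed at 24 to 26 months of age. Livers were frozen, total RNA was isolated, and the hybridised arrays were read on a Hewlett-Packard GeneArray scanner. The 8 samples form 1 group and are numbered here by the replicate number in their titles. No other genotype or diet was analysed here, so no comparison between groups could be made.

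The deposited table gave 1 intensity per probe set and array on a linear scale, for 12488 probe sets. The software that turned scanner images into intensities, its version, its scaling target and its detection calls are not given in the sources used here. All deposited intensities were above 0. The mean intensity after trimming 2% of probe sets at each end differed by only 0.009% between arrays, within the tolerance of 10% fixed for this purpose, so the table was taken as already scaled between arrays and was used as deposited. Scaling to a common trimmed mean makes each level relative to the sum of the others on its array. Scaling to a common median instead shifted whole arrays by between -0.10 (liver 8) and 0.11 (liver 3) on the log2 scale, and quantile normalization shifted none by more than 0.06. Without detection calls, a low signal could not be told from background.

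The 66 control probe sets were kept out of the tests. Of the 12422 others, 10833 carried 1 gene symbol in the platform annotation, 396 carried several and 1193 carried none. Entrez identifiers of 10817 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. No gene was named from a probe set with several symbols. Each gene was represented by its tested probe set with the highest mean signal. Intensities below the 10th percentile of all values, 11.2, were set to it before log2 transformation. Tested probe sets were those with a mean log2 signal above the median of the non-control probe sets, at a signal of 162, which left 6211 probe sets for 4819 genes.

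Tests, gene lists, pairs of lists and the rule for naming genes were fixed before the data were examined. Variability was tested with limma 3.58.1 in R 4.3.3. The variance of each probe set over the 8 arrays was set against an intensity-trended, robust prior and read as an F statistic with 7 degrees of freedom and a prior of 4.90, one-sided, with Benjamini-Hochberg adjustment. On simulated data for 6211 probe sets, this test recovered 87 of 100 probe sets whose standard deviation (SD) was raised 3-fold when all others varied equally, and 2 of 100 when the others varied as unequally as the real ones. For 6-fold raised SDs the counts were 99 and 16 of 100. A further test was therefore added after the data had been seen. It set each variance against the typical variance at that signal, from a loess curve with a span of 0.3 and a chi-square distribution with 7 degrees of freedom, and is called the typical-variance test here. With unequal variances it recovered 87 of 100 probe sets raised 3-fold and 100 of 100 raised 6-fold, and it also called 578 of the 6011 probe sets that had not been raised. Its calls are therefore of genes that varied more than most genes of like signal, for any reason.

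Of 44 gene lists, 38 had at least 3 tested members. Listed symbols absent from the annotation were replaced by a gene that carried them as a synonym. Among others, this put Trh in the place of transferrin (Trf) in the apolipoprotein list and Nckap1 in the place of H19 among fetal and tumour markers. Co-variation of a list was the mean Pearson correlation over all pairs of its members across the 8 arrays. It was set against 10000 random gene lists of the same size, matched on mean signal in 10 bins, one-sided, with adjustment over the 38 lists. The smallest p these random lists can give is 0.0001. On simulated data for 4819 genes, 10 of 10 planted lists and 0 of 28 others were called. The simulated genes varied independently with equal SDs, and each planted list shared a factor of larger SD than that. Real genes do not vary independently, so these counts do not give the power or the false calls in the real data. A list score was the mean of its members' centred log2 signals. Fisher's exact test, one-sided, compared the share of genes past the typical-variance test in a list with that among all tested genes. Relations between 16 fixed pairs of list scores or genes used Pearson's r and Spearman's rho with exact two-sided permutation tests over all 40320 pairings, adjusted over the 14 pairs that could be run. Where the largest gap between neighbouring values, with at least 2 arrays on each side, exceeded 50% of the range on either axis, no pooled correlation was given. Principal components were set against 100 sets in which each probe set was permuted over arrays. The threshold was an adjusted p of 0.05 throughout. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

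Genes were to be named if they had the 25 largest SDs among genes past the limma test, were among up to 4 members past that test in a list, were among the 3 members with the largest SDs in a called list with none, belonged to a fixed set of growth hormone, thyroid and X-linked genes or to a fixed pair, or had the 5 smallest SDs among listed genes. Because the limma test called 0 probe sets, the first part of the rule was applied to the typical-variance test, a choice made after the values were seen. List members cited beyond these were also chosen after their values were seen.

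The alternatives tried were quantile and median scaling, other floors and signal filters, removal of probe sets with shared sequences, other variance models, rank correlation, random lists matched also on SD, the mean of all probe sets of a gene, removal of the first principal component, and each array left out in turn. Added after the data had been seen were the omission of livers 4 and 8, centring within arrays 1 to 4 and 5 to 8, which differed in their spike-in controls, and removal of the relation to an RNA integrity ratio. The labels describe each sample as from a mouse but do not state that the 8 mice or dissections were independent. The exact permutation tests therefore hold for these samples only. P-values of the list, Fisher and variance tests set genes against other genes on the same 8 arrays. They do not measure the spread between mice. The number of arrays limits the precision.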

Results

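The data were expression profiles of the liver of 8 female Ames dwarf mice aged 24 to 26 months with free access to food. Ames dwarf mice lack growth hormone, prolactin and thyroid-stimulating hormone. All 8 samples belonged to 1 group, so the question the data allowed was which genes and gene groups differed from liver to liver. The median intensity of the arrays was 168 ± 7.85 (SD, n = 8) and ranged from 156 in liver 3 to 181 in liver 8. Over the 28 pairs of arrays, the Pearson correlation across 6211 tested probe sets, which are not independent replicates, ranged from 0.907 to 0.973 with a median of 0.955. At most 0.0966% of values were identical between any pair, so no arrays were duplicates of each other. The ratio of 3′ to 5′ control signals, a sign of RNA integrity, was 0.871 ± 0.0499 for Gapdh and 1.56 ± 0.166 for beta-actin (SD, n = 8). It was 4.64 ± 1.98 for the pyruvate carboxylase controls, with the highest ratio, 8.81, in liver 2. The mean log2 signal of the spike-in controls lay between 10.70 and 10.88 on arrays 1 to 4 and between 10.18 and 10.46 on arrays 5 to 8, although the labels named no batch.

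The genes that differed most between livers encoded acute-phase proteins, interferon-induced proteins and antigen-presenting molecules, and nearly all were highest in livers 4 and 8. Saa3, an acute-phase serum amyloid, ranged 93.8-fold, from a signal of 166 in liver 3 to 15526 in liver 4 (4199.7 ± 5839, SD, n = 8). Cxcl9, an interferon-gamma-induced chemokine, ranged 93.9-fold, from 54.2 to 5089.5, and Lcn2, an iron-sequestering protein of the acute phase, ranged 76.7-fold, from 133 to 10195. A further Lcn2 probe set ranged only 2.0-fold and did not follow these values. The guanylate-binding proteins Gbp3 and Gbp2 ranged 61.0-fold and 37.5-fold, Saa2 31.7-fold and Igtp, an interferon-induced GTPase, 25.3-fold. Among the 25 genes with the largest SDs, 8 belonged to the interferon list, 4 to the MHC class II list and 4 to the acute-phase list, 22 were highest in liver 4, and in 21 livers 4 and 8 held the highest values. The exceptions were Adam28, a metalloprotease gene, Cyp2c39, 0610005C13Rik and Scx, a transcription factor of tendon cells. Gbp7, AW112010, Socs1, an inhibitor of cytokine signalling, and Wfdc21 were in no fixed list and ranged 17.2-fold, 11.8-fold, 33.2-fold and 32.5-fold, all highest in liver 4. Folds of genes whose lowest signal was under 162, among them Cxcl9, Lcn2, Gbp3, Gbp2, Socs1 and Wfdc21, are uncertain, because low signals could not be told from background.

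**Figure D1:**
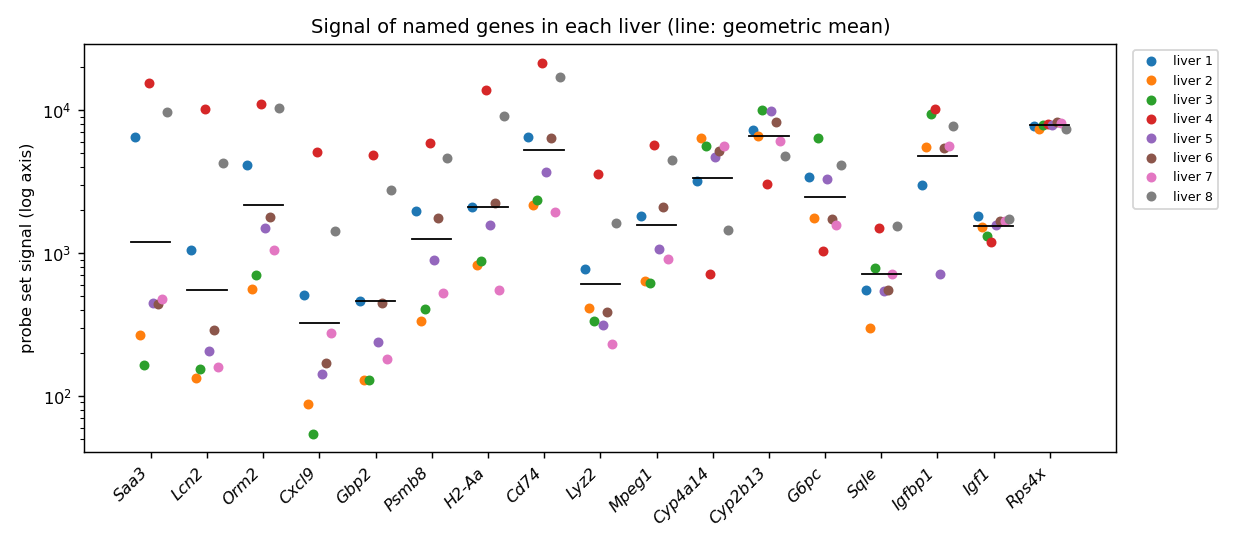
Probe set signal (log axis) of 17 named genes in each of the 8 livers, with 1 coloured point per liver and a black line at the geometric mean. Saa3 spans 166 to 15526 with its highest values in livers 4 and 8, while Rps4x spans 7369 to 8283.

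In the limma test of each variance against the spread of variances, 0 of 6211 probe sets passed after adjustment, the smallest adjusted p was 0.0597 (Saa3), and 425 probe sets (6.84%) had an unadjusted p under 0.05. The typical-variance test, chosen after the values were seen, called 699 probe sets (11.3%) for 493 genes. Of these 493 genes, 186 (37.7%) were highest in liver 4, against 15.4% of the 4326 other genes. Liver 4 was also lowest for 18.3% of the 493 genes and for 22.9% of the others. Counts of list members lowest in liver 4 are to be read against these shares. Among genes with several tested probe sets, the median correlation between probe sets across livers was 0.433 for 79 called genes and 0.216 for 600 others. The limma count turned on the setting, with 21 probe sets past it when those with shared sequences were removed, 10 with median scaling, 4 without liver 2 and 2 without liver 4.

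Interferon-response, MHC class II and macrophage genes each rose and fell together from liver to liver. All 15 tested interferon-response genes varied beyond the typical variance, in all 15 livers 4 and 8 held the highest values, and the members' median range was 12.8-fold. Examples were Psmb8, a subunit of the immunoproteasome, at 336 in liver 2 and 5912 in liver 4, Psmb9 at 291 to 4052, and Iigp1, an interferon-induced GTPase, at 1443 to 18418, with a second Iigp1 probe set ranging 26.7-fold. The list's mean pairwise r was 0.920, against a 95th percentile of 0.0821 for random lists (adjusted p = 0.000633). All 7 MHC class II genes varied likewise, with a mean pairwise r of 0.959 (adjusted p = 0.000633). H2-Aa ranged from 555 in liver 7 to 13951 in liver 4, H2-Ab1 from 311 to 6106, Cd74, the invariant chain, from 1939 to 21571, and H2-DMb1 from 133 to 2272. Of 13 macrophage and Kupffer cell genes, 12 varied and all 13 were highest in liver 4, with a mean pairwise r of 0.890 (adjusted p = 0.000633). Lyz2 ranged 15.3-fold, Cybb 12.3-fold and Mpeg1 9.21-fold, whereas Clec4f, a Kupffer cell lectin, ranged 1.84-fold and was the member that did not pass. In the limma test, 14 of 15, 7 of 7 and 12 of 13 members of these lists passed when adjusted over the list alone, against 0 over all genes. The p behind each adjusted value was the smallest the random lists can give. Without livers 4 and 8, mean pairwise r was 0.758, 0.823 and 0.691, and with the first principal component removed it was 0.175, 0.390 and 0.480. The interferon score also rose with the median intensity of the arrays (r = 0.926, exact permutation p = 0.00062, adjusted over 6 technical measures p = 0.00372, rho = 0.952 with p = 0.00114, r = 0.799 without the 2 livers farthest from the median score, 0.954 centred within arrays 1 to 4 and 5 to 8).

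**Figure D2:**
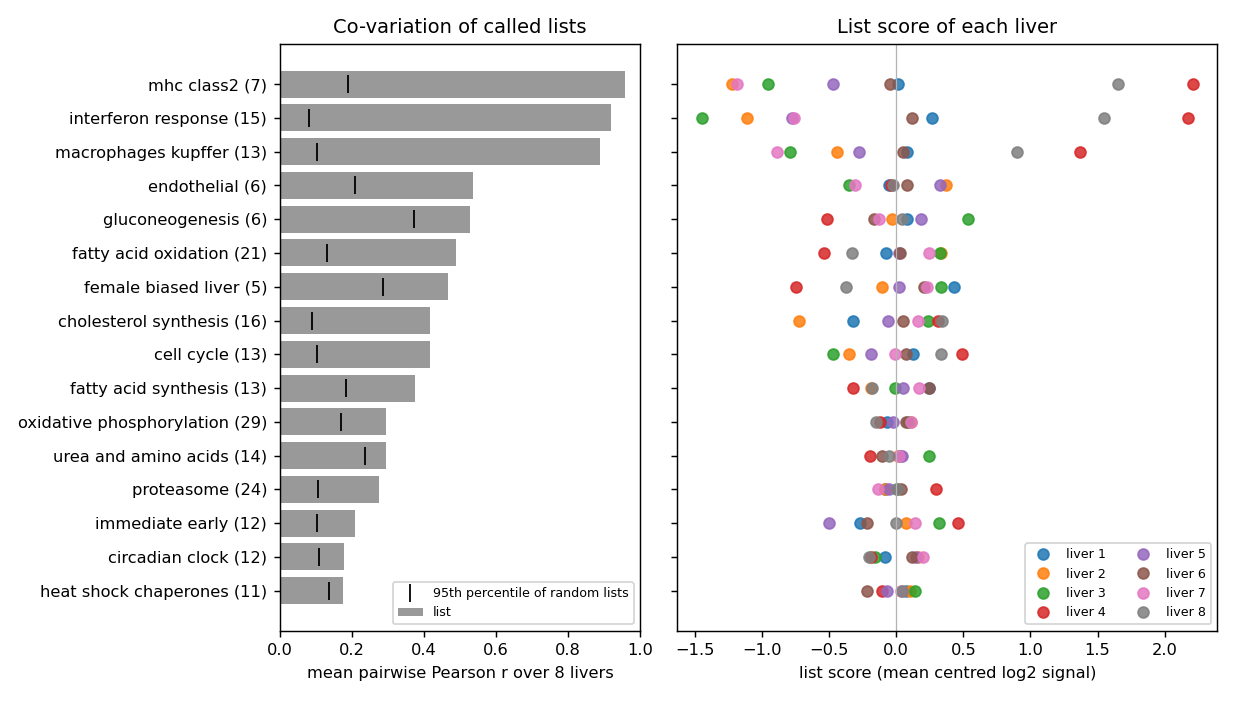
Left, mean pairwise Pearson r of the 16 lists past the threshold (bars, with the number of tested genes), with the 95th percentile of random lists as a black tick. Right, the score of each list in each liver (mean centred log2 signal), which reaches 2.21 for the MHC class II list and 2.17 for the interferon list in liver 4.

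Several acute-phase genes varied strongly, the list as a whole just missed the threshold, and the score of cytochrome P450 and related drug-metabolising genes ran against the acute-phase score. Of 18 acute-phase genes, 8 varied beyond the typical variance and 5 passed the limma test when adjusted over the list alone, against 0 over all genes. Orm2, an acid glycoprotein, ranged from 559 in liver 2 to 11123 in liver 4, and Apcs, serum amyloid P, from 974 to 4516. Of the 18 genes, 11 were highest in liver 4, but others were not. The fibrinogen genes Fga and Fgb, which also varied, were highest in liver 2 (8964 and 11608). Hamp had its lowest signals in livers 8 and 4 (16873 and 17902). Hp, haptoglobin, was at 21796 ± 1882 (SD, n = 8) and Crp at 761 ± 83.8. The list's mean pairwise r of 0.244 did not pass (adjusted p = 0.0528), although it did in 7 of 15 other settings, for example against random lists matched also on SD (adjusted p = 0.0107), and in 3 of 8 runs with an array left out. The list held more variable genes than all tested genes did (Fisher's exact test, adjusted p = 0.00124). By that test 13 lists held more variable genes, among them lists that did not co-vary, namely xenobiotic phase I (adjusted p = 0.00236), growth hormone axis (0.0475) and male-biased genes (0.0491). Of 20 genes of xenobiotic phase I metabolism, 8 varied, 14 were lowest in liver 4, and in 8 both livers 4 and 8 held the lowest signals. The list had a mean pairwise r of 0.186 that did not pass (adjusted p = 0.132) except against random lists matched also on SD (adjusted p = 0.0335). Cyp2b13 ranged from 3054 in liver 4 to 10061 in liver 3, and Nr1i3, which encodes the nuclear receptor CAR, from 3549.8 in liver 4 to 10092 in liver 5. The acute-phase and xenobiotic scores ran in opposite directions over the 8 livers (r = -0.887, exact permutation p = 0.00278, adjusted p = 0.0194). Spearman's rho was -0.833 (exact permutation p = 0.0154, adjusted p = 0.108), and r was -0.618 without livers 4 and 8. With either liver 2, 3, 4 or 8 left out, the adjusted p from exact permutation was 0.0556, 0.0556, 0.156 and 0.0674.

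Lipid and glucose metabolism genes also moved in groups. Of 21 fatty acid oxidation genes, 12 were lowest in liver 4 and 6 varied beyond the typical variance, 10 when adjusted over the list alone (mean pairwise r 0.490, adjusted p = 0.000633). Cyp4a14, a fatty acid hydroxylase and target of the nuclear receptor PPAR-alpha, ranged from 711 in liver 4 to 6396 in liver 2, Vnn1 from 78.7 in liver 4 to 604 in liver 2, and Ppara, which encodes that receptor, from 678 in liver 6 to 3925 in liver 3. This co-variation ended when the first principal component was removed (mean pairwise r -0.0099, adjusted p = 0.633). Cholesterol synthesis genes followed a different order. Of 16 members, 10 were lowest in liver 2 and 10 varied, 11 when adjusted over the list alone (mean pairwise r 0.417, adjusted p = 0.000633). Sqle, squalene epoxidase, ranged from 299.8 (liver 2) to 1554 (liver 8), Msmo1 from 708 (liver 2) to 3263 (liver 3) and Mvd from 57.0 (liver 2) to 368 (liver 7). Fatty acid synthesis genes had a mean pairwise r of 0.374 (13 genes, 5 variable, 6 adjusted over the list alone, adjusted p = 0.0038). Among them, Elovl6 ranged 2.92-fold, Scd2 3.01-fold and Thrsp, a thyroid-responsive regulator of lipid synthesis, 2.98-fold with its lowest value in liver 4. Gluconeogenesis genes had a mean pairwise r of 0.528 (6 genes, 2 variable, also 2 adjusted over the list alone, adjusted p = 0.0261), with 5 of 6 highest in liver 3. G6pc, glucose-6-phosphatase, ranged from 1034 in liver 4 to 6428 in liver 3, Tat from 9274 to 21338 and Pck1 from 4283 to 7734. That call was lost without liver 3 or liver 4, and with the first principal component removed (mean pairwise r 0.217, adjusted p = 0.13).

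Cell cycle, immediate-early, endothelial and female-biased genes also passed as lists. Cell cycle genes had a mean pairwise r of 0.417 (13 genes, 5 variable, 6 adjusted over the list alone, adjusted p = 0.000633), and 10 of 13 were highest in liver 4. Mcm5, a replication helicase subunit, ranged from 59.1 to 459, Stmn1 from 54.5 to 412 and Plk1, a mitotic kinase, from 215 to 548. With the first principal component removed the cell cycle call was lost (adjusted p = 0.182). Immediate-early genes had a mean pairwise r of 0.210 (12 genes, 7 variable, 10 adjusted over the list alone, adjusted p = 0.01). Nr4a1 ranged 11.5-fold and Dusp1 3.92-fold, both highest in liver 3, and Egr1 ranged 5.02-fold, highest in liver 4. Endothelial genes had a mean pairwise r of 0.536 (6 genes, 0 variable, 0 adjusted over the list alone, adjusted p = 0.00109), with Tie1 between 219.5 and 519, Cdh5 between 236 and 511 and Ramp2 between 206 and 477. Female-biased liver genes had a mean pairwise r of 0.466 (5 genes, 4 variable, 5 adjusted over the list alone, adjusted p = 0.0228), and 4 of 5 were lowest in liver 4. Hao2 ranged from 1090.0 in liver 4 to 2856 in liver 7 and Cyp17a1 from 294 in liver 4 to 1130.2 in liver 1. Without livers 4 and 8 the mean pairwise r of this list was -0.0358, and with the first principal component removed its adjusted p was 0.0676.

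The other called lists were those of oxidative phosphorylation, the proteasome, the urea cycle and amino acids, the circadian clock and heat shock chaperones. Oxidative phosphorylation genes had a mean pairwise r of 0.295 (29 genes, adjusted p = 0.00169), with Cycs, cytochrome c, between 272 and 786, Cox6b1 between 165 and 344 and Sdhd between 4128 and 7691. Proteasome genes had a mean pairwise r of 0.276 (24 genes, adjusted p = 0.00143), and 15 of 24 were highest in liver 4. Psme1, an interferon-inducible activator subunit, ranged 4.10-fold, and Psma5 and Psma1 ranged 1.87-fold and 1.84-fold. In each of the last 2 lists 1 gene varied, also 1 when adjusted over the list alone. Urea cycle and amino acid genes had a mean pairwise r of 0.294 (14 genes, 1 variable, also 1 adjusted over the list alone, adjusted p = 0.0423), with Hpd between 319 and 578 and Asl between 229 and 397. The variable gene of this list was Tat, which was also counted among the gluconeogenesis genes. Circadian clock genes had a mean pairwise r of 0.178 (12 genes, 3 variable, 6 adjusted over the list alone, adjusted p = 0.0261), with Nr1d1 between 669 and 1561, Cry1 between 190.4 and 531 and Per1 between 210.1 and 498. Heat shock chaperone genes had a mean pairwise r of 0.177 (11 genes, 0 variable, 0 adjusted over the list alone, adjusted p = 0.0482), with Hsp90aa1 between 1089 and 2384, Hspa1b between 157 and 345 and Hsph1 between 326 and 700. Calls were lost without liver 4 (female-biased, immediate-early and proteasome), without liver 7 (circadian), without any of livers 1, 3, 4, 6 or 7 (urea cycle) or without any of livers 1, 2, 3, 4, 6 or 7 (heat shock). With the first principal component removed, the calls of oxidative phosphorylation (mean pairwise r 0.082, adjusted p = 0.0605), circadian clock (0.0959, adjusted p = 0.155) and heat shock genes (0.151, adjusted p = 0.062) were lost. Of 15 alternatives other than leaving out 1 array, the heat shock list passed in 1, urea cycle in 7, circadian clock in 9, and female-biased, gluconeogenesis and immediate-early lists in 10 each. Only 8 of the 16 lists passed with arrays scaled to the same median: interferon response, MHC class II, macrophages, cell cycle, cholesterol synthesis, fatty acid oxidation, endothelial and oxidative phosphorylation.

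Growth hormone axis genes did not move as a group, but several members differed widely. The list's mean pairwise r was 0.0071 (10 genes, 4 variable, also 4 adjusted over the list alone, adjusted p = 0.559). Igf1, the main growth hormone-dependent growth factor, had a signal of 1569.6 ± 214 (SD, n = 8) and ranged 1.52-fold on its brighter probe set and 3.90-fold on the other. Igfals, the acid-labile subunit that stabilises circulating IGF-1, ranged from 92.7 in liver 3 to 625 in liver 1. Igfbp1, an IGF-binding protein, ranged 14.3-fold, from 709 in liver 5 to 10169.6 in liver 4, and Igfbp2 had a signal of 10375 ± 2697. Ghr, the growth hormone receptor, had a signal of 4658 ± 604. Socs2 (98.0 ± 16.7) and the thyroid hormone deiodinase Dio1, above the floor in 3 of 8 arrays, were below the signal needed for testing. Xist, the X-inactivation RNA of female cells, had signals of 543 to 1494 in the 8 livers. The Y-linked genes Kdm5d and Eif2s3y were above the floor on 3 and 2 arrays, and Uty on 4, with no signal above 69.7. The Sry probe set, whose sequences are shared, read 34.1 to 109.6. The most uniform listed genes were F10, coagulation factor X (4188 ± 157, 1.13-fold), Rps4x (1.12-fold), Psmb3 (1.18-fold), Ndufv2 (1.18-fold) and Rpl10a (1.20-fold).

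The other tested lists showed no co-variation past the threshold in the chosen setting. Mean pairwise r was 0.243 for apolipoproteins and secreted proteins, with Trh in the place of transferrin (adjusted p = 0.0701), 0.365 for periportal hepatocyte genes (0.0734) and 0.146 for pericentral genes (0.356). It was 0.104 for chaperones of the endoplasmic reticulum (0.0963), 0.428 for p53 and senescence genes (0.0963), 0.126 for thyroid hormone-related genes (0.18) and 0.126 for ribosomal proteins (0.333). It was 0.0695 for glutathione and antioxidant genes (0.358), 0.068 for complement and coagulation genes (0.548), 0.0065 for bile acid genes (0.608) and 0.0362 for glucocorticoid and metal stress genes (0.449). With another setting some of these lists passed, namely apolipoproteins in 5 of 15 settings (adjusted p = 0.00326 with the first principal component removed and 0.0218 without livers 4 and 8), thyroid hormone-related genes in 2 of 15, and periportal, endoplasmic reticulum chaperone (0.0471 without livers 4 and 8) and glutathione genes (0.0301 with the first component removed) in 1 of 15 each. Male-biased liver genes had -0.13 (0.941), MHC class I genes -0.0274 (0.729) and fetal and tumour markers, with Nckap1 in the place of H19, -0.0249 (0.661). Among markers of other cell types, it was -0.0189 for stellate cells and fibroblasts (0.666), -0.047 for B and plasma cells (0.666), -0.166 for neutrophils (0.77), 0.0518 for erythroid cells (0.449) and 0.0997 for pancreatic acinar cells (0.333). Markers of T and natural killer cells, cholangiocytes, adipose tissue, skeletal muscle, and adrenal gland and kidney, and the list of sex-linked genes, had fewer than 3 tested members.

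MHC class II and interferon-response scores rose together over the 8 livers (r = 0.973, exact permutation p = 0.000496, adjusted p = 0.00694). Both scores were highest in liver 4, second in liver 8 and below their means in livers 2, 3, 5 and 7. Spearman's rho was 0.881 (exact permutation p = 0.00724, adjusted p = 0.101), and r was 0.856 without livers 4 and 8. Without liver 4 alone the adjusted p from exact permutation was 0.0639. Centred within arrays 1 to 4 and within arrays 5 to 8, each too few for a correlation of its own, r was 0.9735 for this pair and -0.8885 for the acute-phase and xenobiotic scores, with an adjusted exact permutation p of 0.0972 for either.

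**Figure D3:**
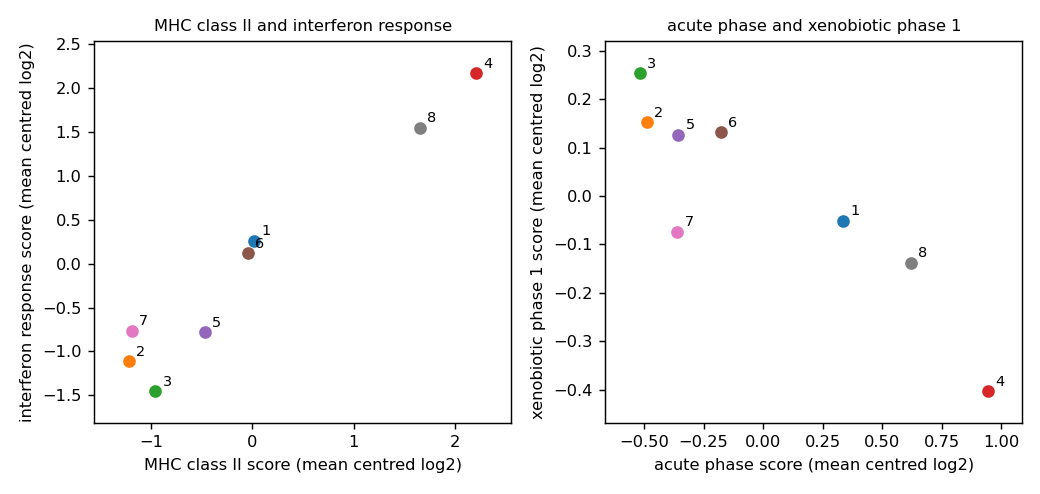
Scores (mean centred log2 signal) of the 8 livers, with each point numbered by liver, for MHC class II against interferon-response genes (left, r = 0.973) and acute-phase against xenobiotic phase I genes (right, r = -0.887). Liver 4 lies at the end of each plot.

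No other fixed pair passed. Acute-phase and endoplasmic reticulum chaperone scores had an r of 0.724 (exact permutation p = 0.0356, adjusted p = 0.0998, rho = 0.69, r = 0.605 without livers 4 and 8), and pericentral and periportal scores 0.748 (exact permutation p = 0.0285, adjusted p = 0.0996, rho = 0.738), which fell to 0.0792 without livers 3 and 4 and was 0.932 without liver 1, where the pair passed (adjusted exact permutation p = 0.00833). Male-biased and female-biased scores had an r of 0.589 (exact permutation p = 0.124, adjusted p = 0.289, rho = 0.571, r = 0.515 without livers 3 and 6). The sign of this r turned without liver 2 (-0.0993), without liver 5 (-0.039), without shared-sequence probe sets (-0.03), above the 25th percentile of signal (-0.196) and with no filter (-0.0995). With arrays scaled to the same median, the pericentral and periportal pair and the male-biased and female-biased pair passed (adjusted exact permutation p = 0.0266 and 0.0493), the latter also above the 75th percentile of signal (r = 0.913, adjusted exact permutation p = 0.0242). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1186 ± 380, SD, n = 8), and Cyp8b1 (2023 ± 369) had an r of 0.0754 (exact permutation p = 0.847, rho = 0.0476, r = -0.0839 without livers 2 and 5). Igf1 and Igfbp1 had an r of -0.392 (exact permutation p = 0.338, adjusted p = 0.526, rho = -0.5, r = 0.248 without livers 3 and 4). For the remaining 6 pairs, among them cholesterol with fatty acid synthesis (-0.129), fatty acid synthesis with oxidation (0.426) and B cell with MHC class II genes (0.401), the adjusted p from exact permutation was 0.526 or more. Igfals separated livers 3 and 4 from the others, so no pooled correlation with Igf1 was given. Among the other 6 livers r was 0.449 (exact permutation p = 0.371, rho = 0.314 with p = 0.564). The pair of macrophage with T and natural killer cell genes and that of Dbp (1466 ± 328) with Arntl (81.2 ± 24.3) were not run, because the T cell list and Arntl were below the signal needed for testing.

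Livers 4 and 8 stood apart along the main direction of variation of the tested probe sets. Log2 signals were centred but not scaled for this, so genes with large SDs weighed most. Many of those genes were named above as highest in these livers, so the component is not independent of them. The first principal component held 39.4% of the variance, against at most 17.2% in 100 permuted sets, and the next components held 18.2% and 12.1%. Loadings on the first component were 0.692 for liver 4 and 0.43 for liver 8, and between -0.346 and 0.0383 for the others. The component rose with the median intensity of the arrays (r = 0.892, exact permutation p = 0.00233, adjusted over 18 relations p = 0.042, rho = 0.929 with p = 0.00223, r = 0.706 without the 2 livers farthest from the median, 0.935 centred within arrays 1 to 4 and 5 to 8). No control ratio, spike-in or 18S ribosomal RNA measure had an adjusted p under the threshold, the smallest from exact permutation being 0.348.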

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

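The search for single livers far from the other 7 covered 129 values. Of these, 79 were of named genes, in part chosen after their values were seen and for large SDs. In all, 5 values stood out, no more than the 1 in 20 that chance gives for independent values not so chosen. They lay in livers 2 to 5, with a pair of them in liver 2, and no explanation was tested for them.

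The proteasome score of liver 4, 0.30, lay far above those of the other livers. The Igfbp1 signal of liver 5, 709, was far below the other 7 on the log2 scale, which lay between 3012 and 10169.6. Liver 2 had isolated low signals for Mvd, an enzyme of cholesterol synthesis (57.0), and Stmn1, a microtubule regulator of dividing cells (54.5). Liver 3 had an isolated low signal for Scx (63.9), whose other values lay between 329 and 1427.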

How the results depend on the processing

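The omission of livers 4 and 8, the use of arrays 1 to 4 and 5 to 8 as a block, the integrity regression and the typical-variance test were chosen after the data had been seen. Of 770 list values under the alternatives fixed in advance, 56 lost the call, 21 gained it and 1 reversed. Of 116 under those added later, 8 lost it, 3 gained it and 1 reversed. For pairs, 7 of 232 and 4 of 26 lost the call, and 5 of 232 gained it. The cholesterol synthesis, endothelial, interferon, macrophage and MHC class II calls held under every alternative run. The mean pairwise r of the female-biased list was -0.0358 without livers 4 and 8, and that of fatty acid oxidation was -0.0099 with the first component removed. Probe sets past the limma test numbered 0 in the chosen setting, 10 with median scaling, 2 above the 75th percentile of signal, 21 without shared-sequence probe sets, 2 with the block, 699 with the typical-variance test and 0 to 4 with an array left out. The typical-variance count was 348 above the 75th percentile, where fewer probe sets were tested, and 585 to 689 with an array left out. Called lists numbered 16, but 8 with median scaling, 10 above the 75th percentile and 10 to 19 with an array left out, the lowest without liver 4. Pairs with a gap over 50% of the range on either axis were not counted as called. Called pairs numbered 2, but 4 with median scaling, 0 with rank correlation, 0 within the block, 0 without livers 4 and 8, where fewer samples remained, and 0 to 2 with an array left out. The first component held 39.4% of the variance, 49.91% above the 75th percentile, 28.01% with no filter and 33.75% to 46.88% with an array left out. The lowest correlation between arrays was 0.907, and 0.8804 above the 75th percentile. Except where fewer probe sets or samples are named, the cause was not tested. Signal over background was not measured, so dim genes stayed untested.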

Other observations

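Except for median scaling and the fixed pair of MHC class II with interferon-response scores, all tests in this part were chosen after the data had been seen. For the interferon list, the predictions of the RNA integrity test and of the test centred within arrays 1 to 4 and 5 to 8 were written before their results. The outcome of the centred test could be foreseen from scores already seen, because livers 4 and 8 lie in different sets of arrays. Set against the interferon score, 11 of 37 other lists passed, 7 rising and 4 falling with it. The acute-phase score, in which Saa3, Lcn2, Saa2 and Orm2 weighed most by their large SDs, rose with it (r = 0.973, exact permutation p = 4.96e-05, adjusted p = 0.00138, rho = 0.976, r = 0.879 without the 2 livers farthest from the median interferon score), with 14 of 18 members going that way. So did the cell cycle score (r = 0.958, exact permutation p = 7.44e-05, adjusted p = 0.00138, rho = 1.0, and 0.927 without those livers), with 12 of 13 members going that way, and the macrophage score (r = 0.967, exact permutation p = 0.000471, adjusted p = 0.00367, rho = 0.857, and 0.831 without them). The MHC class I score rose too (r = 0.906, exact permutation p = 0.00389, adjusted p = 0.018, rho = 0.952, and 0.927 without them), with 3 of 4 members going that way, although the list did not co-vary, and with H2-K1 between 10053 and 22157 and H2-D1 between 9179 and 18128. The stellate and fibroblast score had an r of 0.870 (exact permutation p = 0.0059, adjusted p = 0.0232, rho = 0.929, and 0.774 without them), with 8 of 12 members going that way, although that list did not co-vary as a whole. Among its members, the fibrillar collagen Col1a1 (153 to 806) and Col3a1 (106 to 454) were highest in liver 4, and Col1a2 (1312.5), Des (139) and Reln (444) had their lowest signals there. The neutrophil score passed through Lcn2 alone (adjusted exact permutation p of rho = 0.0939), the only 1 of its 3 members to go that way.

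Fatty acid oxidation genes fell as the interferon score rose (r = -0.969, exact permutation p = 0.000223, adjusted p = 0.00275, rho = -0.905 with an adjusted p of 0.0338, and -0.862 without the 2 farthest livers), with 20 of 21 members going that way. Oxidative phosphorylation genes did so too (r = -0.849, exact permutation p = 0.00627, adjusted p = 0.0232, rho = -0.762 with an adjusted p of 0.113, and -0.563 without them), as did xenobiotic phase I genes (r = -0.873, exact permutation p = 0.00355, adjusted p = 0.018, rho = -0.881 with an adjusted p of 0.0383, and -0.563 without them) and urea cycle and amino acid genes (r = -0.801, exact permutation p = 0.0118, adjusted p = 0.0398, rho = -0.714 with an adjusted p of 0.152, and -0.697 without them). The fatty acid oxidation score ranged 1.83-fold between livers, the xenobiotic score 1.58-fold, the urea cycle score 1.35-fold and the oxidative phosphorylation score 1.20-fold. The range of the oxidative phosphorylation score, 0.264 on the log2 scale, was of the order of the shifts of -0.10 to 0.11 under median scaling. The stellate and fibroblast score (0.45) and the MHC class I score (0.47) also had small ranges. Median scaling moved liver 4 by -0.08, liver 8 by -0.10 and liver 3 by 0.11, which lessens rises with the interferon score and deepens falls. Under it the mean pairwise r of cell cycle genes was 0.284, against 0.417. Relations to the interferon score are not given under that scaling. Centred within arrays 1 to 4 and 5 to 8, r was 0.985 for the acute-phase score and -0.969 for fatty acid oxidation. Endothelial genes had an r of -0.0161 with the interferon score (exact permutation p = 0.972, rho = -0.0238).

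The joint rise of interferon-response genes in livers 4 and 8 was set against RNA integrity, a difference between sets of arrays and tissue composition. With the relation of every gene to the pyruvate carboxylase 3′ to 5′ ratio removed, the interferon list kept a mean pairwise r of 0.923. This was larger than in any of 10000 random lists, which argues against RNA integrity as read from that ratio. Centred within arrays 1 to 4 and 5 to 8 the list kept 0.928, also larger than in any random list. Centring could take little from the pattern, because livers 4 and 8 lie in different sets. A high score in a liver of either set argues against a difference between these sets of arrays. The score followed the median intensity of the arrays (r = 0.926), but scaling to a common median moved arrays only by -0.10 to 0.11, against a score range of 3.62, and left a mean pairwise r of 0.9084, which argues against unequal scaling as the whole cause. A lower share of hepatocytes with all other cell types raised alike would raise endothelial with macrophage markers. The slope of the endothelial on the macrophage score was 0.052, and between -0.024 and 0.127 with any array left out. These markers therefore did not rise jointly. The slope cannot decide on a rise of immune cells alone, which need not raise endothelial markers. Nor can it decide if macrophage genes also changed within cells, which would lower the slope. Periportal and pericentral hepatocyte scores fell as the interferon score rose (r = -0.749 and -0.769). They fell short of the threshold (adjusted exact permutation p = 0.0812 and 0.0657), with 8 of 8 and 5 of 6 members going that way. Tissue composition therefore stays open. An inflammatory or infectious state of some of these aged mice is a hypothesis that stays open, as no group in the design bears on it, so no biological explanation was tested.

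The signal of the beta-actin control probe sets also differed between arrays, by 7.21-fold at the 3′ end, from 2167 in liver 6 to 15624 in liver 4, while Gapdh ranged 1.36-fold. Degradation from the 5′ end would make the slope of the 5′ on the 3′ log2 signal clearly larger than 1, but it was 1.051 (0.99 to 1.206 with any array left out). The amount of labelled RNA, read from the spike-in controls, had an r of 0.55 with the actin signal (exact permutation p = 0.158, 0.354 to 0.835 with any array left out), which is too loose over 8 arrays to decide for or against it. The actin signal followed the 18S ribosomal RNA controls (r = 0.947, exact permutation p = 0.000347, rho = 0.976, r = 0.834 without the 2 farthest arrays, 0.922 centred within arrays 1 to 4 and 5 to 8), and the other tested Actb probe sets ranged 3.01-fold and 2.66-fold. Why these controls differ remains open, and no biological explanation was tested.

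Cyp2c39, a retinoic acid hydroxylase, took values in separate ranges, with signals of 6689.7, 6862, 7795 and 7319 in livers 2, 3, 5 and 6 and of 1385, 967, 1187 and 1093 in livers 1, 4, 7 and 8. The related Cyp2c38 ranged from 3239.9 to 10517 and Cyp2c29 from 664 to 1447. The transcript 0610005C13Rik had signals of 433 in liver 4 and 731 in liver 6, and between 2862 and 6034 in the others. These values were singled out after they had been seen.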
